A study of Homo sapiens with 6 samples.

How the data were processed

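RNA-seq was measured in 6 libraries of the lung cancer cell line H2122, 3 labelled SMARCA4 knockout and 3 labelled parental, all from vehicle-treated cells. The deposited files give raw read counts per gene symbol, 1 file per library, with 59050 symbols and 5 classes of unassigned reads at the end of each. Per the labels, the authors used TopHat2 2.1.1, HTSeq 0.11.0 and the hg38 build; the annotation release, strand setting and filters are not given in the sources used here. The counts were whole numbers with no scaling. The 5 unassigned classes were kept out of library sizes and tests and held between 13.8% and 15.3% of each file's reads. Gene reads ranged from 55120937 to 59917980 per library, and 3 counts, taken as the limit of detection per library, correspond to 0.0501 to 0.0544 CPM.

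Counts were filtered with edgeR's filterByExpr at its defaults, scaled by TMM and tested with edgeR 4.0.16 (robust quasi-likelihood F-test, two-sided) in R 4.3.3, with group as the only term. P-values were adjusted by Benjamini-Hochberg over the 17809 genes tested, with a threshold of 0.05. The standard error of a log2 fold change was derived from the quasi-likelihood F value. Positions are from GENCODE 29 on GRCh38 (hg38), matched by symbol for 17395 of the genes tested. Where a group had 1 to 3 reads in all, the ratio of CPM with its 95% counting interval is given; with 0 reads, a bound against 3 counts over the group is given.

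The tests, the 48 gene lists and the rule for naming genes were chosen before the data were examined. Named genes were the set of genes tied to the question; the 10 rising and 10 falling genes with the largest log2 fold change among those passing, with a mean of at least 5 CPM and no overlap between groups; and up to 3 passing members of each list with the smallest adjusted p, or 2 members with the highest mean CPM where none passed. This gave 145 genes, of which 61 share annotated exon bases with another gene and 2 share at least 50% of them. The list members SS18, OAS1, KIF23 and RPL6 were not analysed here. The results of 1 list and of 1 of the 10 rising genes are not used here, though they remain in the counts of lists and genes. Lists with at least 5 tested members were tested with camera of limma 3.58.1 at a preset correlation of 0.01, adjusted over 47 lists, and again with an estimated correlation and with fry. The lists cover SWI/SNF subunits, innate sensing, interferon and antigen presentation, cytokines, signalling, lineage, cell cycle, metabolism and stress, with lists of other cell types and technical lists beside them.

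The fit was tested on simulated data with a spread per gene estimated from these libraries. It recovered 77.3% of genes changed 4-fold, 17.9% of those changed 2-fold and 0% of those changed 1.5-fold. Of its 68 calls, 5 were of unchanged genes. Only 66 or 67 of 17809 genes were changed at each size, against 27.6% of genes called in the data. The adjusted threshold was therefore stricter in the simulation, and these shares are not those of the real comparison. The simulation also gave both groups the same spread for each gene and had no library standing apart. It therefore does not test the fit with a library such as parental replicate 3. Camera called the list that was raised and 0 of 40 random lists. The simulated genes were drawn independently, so this does not test camera on lists whose members vary together.

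The alternatives were RLE and upper-quartile factors, no low-count filter, at least 1 CPM in 3 libraries, DESeq2 1.42.0, limma-voom, the replicate number as a block, each library left out in turn, and for lists an estimated correlation and fry. All 10 divisions of the 6 libraries into 3 and 3 were also fitted. For neighbouring genes, the medians of 137 windows of 20 Mb with at least 20 protein-coding genes at a mean of at least 10 CPM were compared with 2000 permutations of gene positions. For families, symbols sharing a root with at least 8 protein-coding genes were compared with all others by Fisher's exact test. Both scans were added after the data were examined. GC content and gene length were fitted with splines of 5 degrees of freedom.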

Results

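RNA-seq read counts per gene were analysed for 6 libraries of H2122, a human lung cancer cell line. The labels give 3 libraries of a SMARCA4 knockout and 3 of the parental line, all from vehicle-treated cells. Each library held between 55120937 and 59917980 reads assigned to genes. The limit set by 3 counts therefore lay between 0.0501 and 0.0544 CPM, the counts scaled to a common library size, and limits of this kind cover counting error only. Levels are given as CPM after TMM scaling, as mean ± SD with n = 3 libraries per group, and changes as the log2 fold change of the knockout less the parental libraries. The labels do not state whether replicates were separate cultures, so p-values measure only the spread between these samples, which can be technical. The sample titles also carry a number that is 1 in all 3 knockout titles and 1, 3 and 6 in the parental ones, with no statement of what it marks. If it marks a clone, the 3 knockout libraries are repeats of a single clone, and what is particular to that clone is not separated from the knockout.

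SMARCA4 encodes an ATPase of the SWI/SNF chromatin remodelling complexes, and the comparison asks which genes differ when it is knocked out, with the STING pathway named in the title of the series. SMARCA4 (chromosome 19, 10960825 to 11079426 on GRCh38) stood at 20.7, 19.3 and 24.9 CPM in the knockout libraries and at 232, 214 and 335 CPM in the parental ones. That is a log2 fold change of -3.59 (SE 0.22, edgeR quasi-likelihood adjusted p = 0.000176). SMARCA2, which encodes the alternative ATPase of the same complexes, was measured at 67.7 ± 2.43 CPM in the knockout and 67.1 ± 7.30 CPM in the parental group (log2 fold change 0.01, adjusted p = 0.943). STING1, listed under its older symbol TMEM173 (chromosome 5, 139475534 to 139482935), encodes the adaptor of cytosolic DNA sensing and fell from 19.6 ± 6.19 to 1.25 ± 0.0748 CPM (log2 fold change -3.97, SE 0.27, adjusted p = 0.000226). The epithelial cadherin gene CDH1 fell from 341.1 ± 174 to 5.56 ± 0.105 CPM (-5.94, adjusted p = 0.000553), and the intermediate filament gene VIM rose from 0.309 ± 0.223 to 33.98 ± 0.718 CPM (6.77, adjusted p = 0.000635). The counts of both genes differed between parental libraries, with CDH1 at 441, 442 and 140.0 CPM and VIM at 0.455, 0.419 and 0.0528 CPM.

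**Figure D1:**
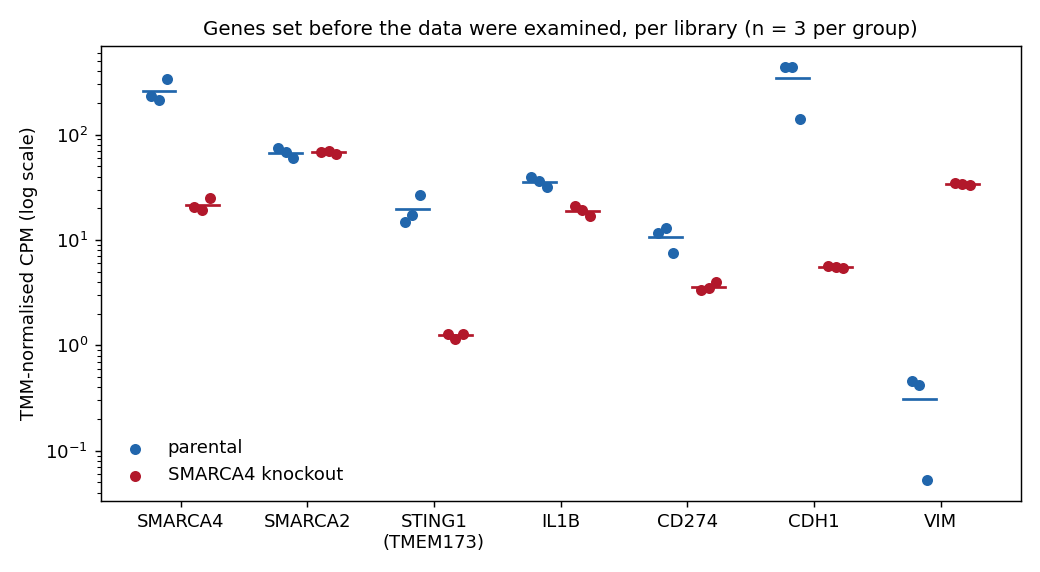
TMM-normalised CPM on a log axis for 7 genes, with parental libraries in blue and SMARCA4 knockout libraries in red; each point is 1 library and each bar the mean of 3. The 3 knockout libraries lay below the 3 parental ones for SMARCA4, STING1, IL1B, CD274 and CDH1 and above them for VIM, while the groups overlapped for SMARCA2.

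Of 17809 genes tested, 4912 changed at an adjusted p under 0.05 by edgeR's quasi-likelihood test, with 2365 rising and 2547 falling. Which direction had more genes depended on the setting: 2138 rose and 2792 fell with RLE factors, 2602 and 2375 with upper-quartile factors, and 1871 and 2833 with no low-count filter. Among the 4912, 3031 changed at least 2-fold. At least 16-fold changes were less even, with 130 genes rising and 467 falling. The groups did not overlap for 4900 of the 4912 changed genes and for 49.8% of all genes tested, where chance gives 10%. The libraries separated by group along the first principal component, which held 76.5% of the variance. Parental replicate 3 stood apart from the other 5 libraries along the second, which held 19.0%. Without parental replicate 3, 11325 of 18372 genes tested changed, 5665 rising and 5660 falling, and these held 4895 of the 4912 genes. Counts of list members in that fit are to be read against these counts over all genes. The filter then also kept more members of some lists. It kept 30 for the mesenchymal list, 25 for cytokines, 24 for lung lineage and 15 for AP-1 factors. With any one of the knockout libraries left out, between 2692 and 2785 genes changed.

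In the list of cytosolic DNA sensing and STING, 8 of 19 tested members fell, none rose and 11 did not pass, and the count adjusted over the list alone was also 8 falling. That none rose depended on parental replicate 3, without which 4 rose and 10 fell. IFI16, a DNA sensor, fell from 79.9 ± 10.6 to 3.06 ± 0.1095 CPM (-4.71, adjusted p = 1.85e-05). The kinase gene IKBKE fell from 37.9 ± 2.84 to 13.9 ± 1.19 CPM (-1.45, adjusted p = 0.00042). The list's median was -0.13, with TBK1 (0.01) and SAMHD1 (0.07), named after their values were seen, among those that did not pass. Its camera test was called down (adjusted p = 0.00783), but adjusted p = 0.231 with an estimated correlation. CGAS, which encodes the DNA sensor upstream of STING, had 4, 4 and 0 reads in the knockout libraries and 0 in each parental library, so it lay at or near the limit of 3 counts and was not tested. In the list of RNA sensing, 7 of 15 members fell, none rose and 8 did not pass; adjusted over the list alone, 7 fell and 1 rose. DHX58 changed by -3.84 (adjusted p = 9.74e-05), MX1 by -2.79 (0.0025) and DDX58 by -0.73 (0.00783). The DDX58 call was lost without knockout replicate 1 or 2, at an adjusted p of at most 0.0524. The list's median was -0.37, and -0.59 without parental replicate 3, where 1 member rose and 12 fell. Camera called this list down at an adjusted p = 0.00479, and adjusted p = 0.262 with an estimated correlation.

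Of 40 tested members of the type I list, 25 fell, 1 rose and 14 did not pass; adjusted over the list alone, 26 fell and 1 rose. The median was -0.98 and the camera adjusted p = 3.06e-08, with adjusted p = 0.21 with an estimated correlation. SAMD9L fell from 39.98 ± 4.20 to 11.99 ± 0.2004 CPM (-1.74, adjusted p = 0.00021) and TRIM22 from 2.099 ± 0.191 to 0.361 ± 0.0566 CPM (-2.53, adjusted p = 0.000442). MX2 had 1 read in the 3 knockout libraries together against 231 in the parental ones, a ratio of 229 with a 95% counting interval of 40.7 to 9076; its log2 fold change of -7.39 became -9.25 without knockout replicate 3, which held that read. The riser was IFI6, named after its values were seen, at 0.98. Of 23 members of the interferon-gamma list, 10 fell, 2 rose and 11 did not pass (11 and 4 adjusted over the list alone). APOL1 changed by -4.98 (-4.37 without parental replicate 3), CASP1 by -3.12 and IL15, a cytokine, by 2.12. That list did not pass camera (adjusted p = 0.0653, and adjusted p = 0.262 with an estimated correlation), but passed without parental replicate 1 or 2, with adjusted p ranging from 0.0267 to 0.102 over the 6 libraries left out in turn. It also passed with no low-count filter (0.00195), with the replicate block (0.0296) and by fry (0.00356), where the other settings ranged up to 0.317. IFNB1 had 0 reads in all 6 libraries, CXCL10 had 1, 1 and 3 reads in the knockout and 4, 3 and 3 in the parental libraries, and CCL5 had between 4 and 9 reads, so no change of these genes was detectable at this depth. With parental replicate 3 left out, 4 genes of the type I list rose and 28 fell, and 7 of the interferon-gamma list rose and 11 fell.

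Of 21 genes of MHC class I antigen presentation, 10 fell, none rose and 11 did not pass, with the same 10 falling when adjusted over the list alone. HLA-B fell from 44.1 ± 12.3 to 12.04 ± 0.359 CPM (-1.87, adjusted p = 0.002), HLA-F changed by -1.10 (0.00471), and B2M, the light chain of class I molecules, fell from 375.8 ± 27.7 to 239.9 ± 8.09 CPM (-0.65, 0.00598). HLA genes resemble each other closely and their counts are uncertain for that reason. Camera gave an adjusted p = 0.00479 for the list, and adjusted p = 0.365 with an estimated correlation. Of the class II list 4 members were tested, too few for a list test, of which CTSS fell (-3.70, adjusted p = 0.000778) and 3 did not pass; adjusted over the list alone, 1 fell. Among cytokines and chemokines, 8 of 23 fell, 4 rose and 11 did not pass (9 and 4 adjusted over the list alone). TGFB2 rose from 3.32 ± 0.450 to 27.5 ± 1.81 CPM (3.05, adjusted p = 7.48e-05), while CXCL16 changed by -1.67, TNFSF15 by -3.20 and IL1B by -0.92 (adjusted p = 0.00399). This list was not called (camera adjusted p = 0.233, and adjusted p = 0.571 with an estimated correlation). It was called down without parental replicate 3 (median -0.72 in place of -0.38, 0.0468) and by fry (0.0253). Among NF-kB targets, 5 of 32 fell, 4 rose and 23 did not pass, with the same counts adjusted over the list alone; NFKBIZ changed by -1.66 and SOD2 by 1.26 (camera adjusted p = 0.768). Among immune checkpoint and natural killer ligand genes, 7 of 22 fell, 5 rose and 10 did not pass (8 and 5 adjusted over the list alone; camera adjusted p = 0.768). CD274, which encodes PD-L1, fell from 10.8 ± 2.91 to 3.62 ± 0.357 CPM (-1.58, adjusted p = 0.00469), LGALS9 changed by -1.78 and TNFRSF14 by -1.88. The counts rising and falling without parental replicate 3 were 4 and 12 for MHC class I, 1 and 1 for class II, 8 and 14 for cytokines, 12 and 12 for NF-kB targets, and 10 and 11 for checkpoint and natural killer ligand genes.

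Of 37 members of the epithelial junction and identity list, 32 fell, none rose and 5 did not pass (33 fell adjusted over the list alone), and the median was -2.32. KRT19, a keratin of simple epithelia, fell from 1344 ± 114 to 31.8 ± 0.689 CPM (-5.40, adjusted p = 8.98e-06). The keratin genes KRT7 and KRT8 of the same list, named after their values were seen, fell less and stayed high. KRT7 went from 2420 ± 172.6 to 1343 ± 18.4 CPM (-0.85) and KRT8 from 1656 ± 429.5 to 1020 ± 73.1 CPM (-0.70, edgeR adjusted p = 0.0467). ST14, a membrane serine protease, fell from 456.7 ± 29.6 to 16.5 ± 0.337 CPM (-4.79) and MARVELD3, a tight junction gene, from 35.2 ± 0.452 to 0.810 ± 0.0803 CPM (-5.44). Camera called the list down (adjusted p = 1.15e-26), and adjusted p = 0.0226 with an estimated correlation. Of 25 mucin and secretory genes, 22 fell, 2 rose and 1 did not pass, with the same counts adjusted over the list alone and a median of -3.03. The mucin genes MUC5AC (474.5 ± 136 to 22.9 ± 1.93 CPM, -4.37), MUC4 (-8.62, and -9.24 without knockout replicate 3) and MUC20 (-4.70) were among them. This list was also called down by camera (adjusted p = 1.35e-13, and adjusted p = 0.0226 with an estimated correlation). Of 25 squamous and stratified keratin genes, 13 fell, 1 rose and 11 did not pass (17 and 4 adjusted over the list alone), with KRT6A at -4.39, SPRR3 at -6.15 and SPRR1B at -6.42. Its camera adjusted p = 0.000409, and adjusted p = 0.262 with an estimated correlation. Parental replicate 3 stood apart in this list, at a centred median of 0.19 against 1 and 1.03 in the other parental libraries, and without it 18 members fell, 6 rose and the median of -1.42 became -1.86. KRT6A and the SPRR genes have close paralogs, which can exchange reads.

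Of 29 tested members of the mesenchymal list, 16 rose, 3 fell and 10 did not pass, with the same counts adjusted over the list alone and a median of 0.55. ZEB1, a transcriptional repressor of CDH1, rose from 1.95 ± 0.867 to 41.9 ± 2.18 CPM (4.43, adjusted p = 0.000557), and LOXL2, a lysyl oxidase, from 14.1 ± 0.866 to 39.4 ± 1.17 CPM (1.49, adjusted p = 0.000218). The fallers were PRRX1, FN1 and COL1A1 (-2.98, -2.44 and -1.46), named after their values were seen. Camera gave an adjusted p = 0.000437 for a rise, and adjusted p = 0.262 with an estimated correlation. Without parental replicate 3, where the list's centred median stood at -0.93 against -0.37 and -0.33 in the other parental libraries, 19 members rose and 8 fell, and the median was 0.96. Of 38 extracellular matrix and integrin genes, 15 rose, 7 fell and 16 did not pass (18 and 8 adjusted over the list alone). LAMC1, a laminin chain, rose from 407.1 ± 25.2 to 1197 ± 62.5 CPM (1.56) and FBN1 changed by 1.72, while TIMP3, an inhibitor of matrix proteases, changed by -4.22. The list's median was 0.43 but its mean was -0.06. Its camera call (adjusted p = 0.0485, and adjusted p = 0.889 with an estimated correlation) was lost with upper-quartile factors (0.0715), limma-voom (0.0576) and fry (0.145), and turned to a fall that did not pass without parental replicate 3 (0.321), where 21 members rose and 15 fell.

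**Figure D2:**
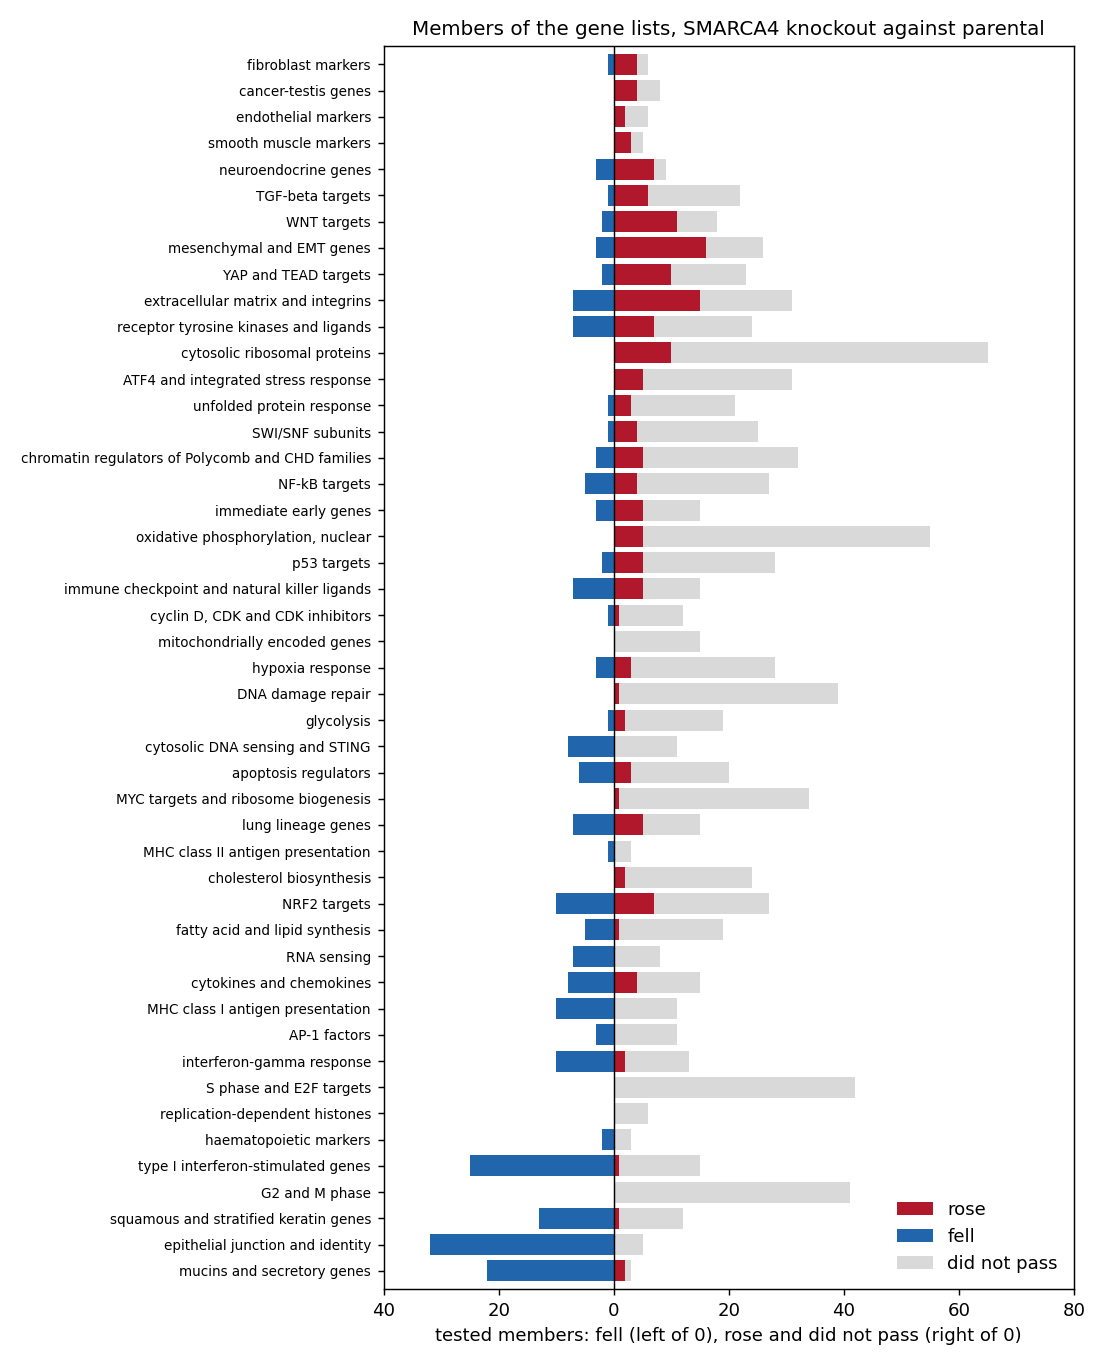
Number of tested members of each of 47 gene lists that fell (blue, left of 0), rose (red, right of 0) or did not pass (grey, right of 0) in the SMARCA4 knockout against the parental libraries, ordered by the median log2 fold change from highest to lowest. In the epithelial list 32 of 37 members fell, while all 41 members of the G2 and M phase list did not pass.

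Markers of other cell types moved in both directions. Of 7 fibroblast markers, 4 rose, 1 fell and 2 did not pass (5 rising and 1 falling adjusted over the list alone), with LUM at 6.18, MFAP5 at 5.74 and COL3A1 at 5.00 (6.76 and 6.78 without parental replicate 3), and COL1A1 at -1.46 (camera adjusted p = 0.00783, and adjusted p = 0.365 with an estimated correlation). Of 5 smooth muscle markers, 3 rose and 2 did not pass (4 rising adjusted over the list alone). TAGLN rose from 19.7 ± 14.5 to 255.7 ± 3.88 CPM (3.70, adjusted p = 0.017), a call lost without any one knockout library (at most 0.058). The camera adjusted p of that list was 0.0362, and adjusted p = 0.262 with an estimated correlation; the call was also lost with limma-voom (0.0557), and the median of 1.05 became 1.95 without knockout replicate 2. Of 6 endothelial markers, 2 rose, SOX18 (2.13) and CDH5 (2.74), and 4 did not pass (3 rising adjusted over the list alone). The list's camera adjusted p = 0.0452 became adjusted p = 0.262 with an estimated correlation, and the call was lost without any one knockout library or parental replicate 3 (at most 0.423, where the median of 1.31 became 0.63). It was also lost with upper-quartile factors (0.0534), no low-count filter (0.193) and limma-voom (0.063). The CDH5 call was lost without knockout replicate 1 or 3 or parental replicate 1 (at most 0.0641), and its log2 fold change ranged from 2.22 to 3.67 with 1 library left out. Of 5 haematopoietic markers, LYZ (-2.62) and CD79A (-2.51) fell and 3 did not pass, with the same counts adjusted over the list alone. Camera gave an adjusted p = 0.0458, and adjusted p = 0.262 with an estimated correlation, and the call was lost without knockout replicate 2 or parental replicate 3 (at most 0.655) and with no low-count filter (0.25). In the fit without parental replicate 3, 4 of 7 tested endothelial markers rose and 2 fell, and 6 of 7 smooth muscle markers rose.

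Of 20 WNT targets, 11 rose, 2 fell and 7 did not pass (11 and 3 adjusted over the list alone; camera adjusted p = 0.00783, and adjusted p = 0.231 with an estimated correlation). DKK1, a secreted WNT antagonist, rose from 27.3 ± 8.90 to 138.5 ± 5.17 CPM (2.34, adjusted p = 0.00152), NOTUM changed by 5.45 and NKD2 by 1.56. Of 25 YAP and TEAD targets, 10 rose, 2 fell and 13 did not pass (12 and 2 adjusted over the list alone), with ANKRD1 at 6.24 and CRIM1 at 1.44 (184.3 ± 13.4 to 501.1 ± 13.2 CPM). Camera gave an adjusted p = 0.00201, and adjusted p = 0.778 with an estimated correlation. The list's centred median was -0.81 in parental replicate 3 and -0.06 and -0.13 in the other parental libraries, and without that library 17 members rose and 6 fell. Of 23 TGF-beta targets, 6 rose, 1 fell and 16 did not pass, with the same counts adjusted over the list alone, and ID3 rose from 52.4 ± 19.0 to 224.7 ± 15.6 CPM (2.1). The camera adjusted p was 0.00783, and adjusted p = 0.743 with an estimated correlation; fry did not call the list (0.0669). Without parental replicate 3, where the list's centred median stood at -1 against -0.03 in both other parental libraries, 15 members rose and 7 fell, and the median of 0.65 became 0.38. Among receptor tyrosine kinases and ligands, 7 of 31 rose, 7 fell and 17 did not pass (12 and 8 adjusted over the list alone; camera adjusted p = 0.508). FGFR1 changed by 2.29, ERBB3 by -2.71 and EPHA1 by -5.78. Of 14 AP-1 factor genes, 3 fell, none rose and 11 did not pass, with the same counts adjusted over the list alone and FOS at -2.50. BATF had 1 read in the knockout libraries and 761 in the parental ones, a ratio of 754 (95% counting interval 134.9 to 29810), and its log2 fold change of -9.10 became -10.99 without knockout replicate 1, which held that read. The AP-1 list gave a camera adjusted p = 0.152, and was not called with an estimated correlation (0.821) or by fry (0.126). It was called down without parental replicate 3 (0.0122) and with no low-count filter (0.0491). Of 18 immediate early genes, 5 rose, 3 fell and 10 did not pass, with the same counts adjusted over the list alone; NR4A3 changed by 2.94 and ZFP36 by -1.06 (camera adjusted p = 0.701). The counts rising and falling without parental replicate 3 were 12 and 7 for WNT targets, 16 and 11 for receptor tyrosine kinases and ligands, 2 and 11 for AP-1 factors, and 8 and 9 for immediate early genes.

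Lineage genes changed in both directions. Of 22 lung lineage genes, 7 fell, 5 rose and 10 did not pass (8 and 5 adjusted over the list alone; camera adjusted p = 0.435). The pioneer factor genes FOXA1 (150.9 ± 10.1 to 69.3 ± 1.38 CPM, -1.12) and FOXA2 (-5.47, and from -6.11 to -5.00 with 1 library left out) fell, and ABCA3, a lipid transporter of alveolar cells, changed by 1.01. Of 12 neuroendocrine genes, 7 rose, 3 fell and 2 did not pass, with the same counts adjusted over the list alone. The camera adjusted p was 0.13, and 0.365 with an estimated correlation, but 0.0147 with at least 1 CPM in 3 libraries and 0.00195 by fry. SNAP25 changed by 4.75 and SYP by 2.82, and CHGA had 2 reads in the knockout and 52 in the parental libraries, a ratio of 25.8 (95% counting interval 6.78 to 218.3). Of 8 cancer-testis genes, 4 rose and 4 did not pass, with the same counts adjusted over the list alone, among them MAGEC2 (1.98) and MAGEA3 (5.13). MAGEA12 had 279 reads in the knockout and 2 in the parental libraries, a ratio of 140.8 (38.6 to 1169), and both parental reads lay in parental replicate 3, without which the log2 fold change of 6.89 became 9.53. Counts of the MAGEA genes are uncertain because of near-identical copies. Camera called that list up at an adjusted p = 0.00201, and adjusted p = 0.231 with an estimated correlation; its median of 1.31 became 0.73 without parental replicate 1. Of 26 SWI/SNF subunit genes, SMARCA4 fell, 4 rose and 21 did not pass, with the same counts adjusted over the list alone (camera adjusted p = 0.508). Without parental replicate 3, 10 of them rose and 9 fell, in a fit that called more genes of all kinds in both directions. SMARCD3 rose from 8.79 ± 0.805 to 20.04 ± 3.84 CPM (1.19, adjusted p = 0.00415). Of 35 Polycomb, CHD and related chromatin regulators, 5 rose, 3 fell and 27 did not pass, with the same counts adjusted over the list alone (camera adjusted p = 0.508). SMARCA1 changed by 1.46, SMARCAL1 by 0.72 and CHD4 by -0.65; CHD4 shares 53.5% of its annotated exon bases with other genes and was not called without knockout replicate 2 (at most 0.0546). The counts rising and falling without parental replicate 3 were 12 and 10 for Polycomb and CHD regulators, 6 and 12 for lung lineage genes, 7 and 4 for neuroendocrine genes, and 6 and 0 for cancer-testis genes.

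Proliferation genes differed more among the parental libraries than between the groups. None of 42 S phase and E2F targets and none of 41 G2 and M phase genes changed by edgeR, with 0 also adjusted over the list alone; at an unadjusted p under 0.05 these counts were 1 and 0, by DESeq2 1 and 0, and by limma-voom 0 and 0. The median log2 fold changes were -0.74 and -1.27 (camera adjusted p = 0.178 and 0.204). MKI67, a marker of cycling cells, was at 114.5 ± 10.51 CPM in the knockout and 275.8 ± 352.3 CPM in the parental group (-1.27, adjusted p = 0.355), and TOP2A was at -0.61 (0.604); without parental replicate 3 they were at 0.61 (0.00082) and 0.90 (8.34e-08). In parental replicate 3 these genes were higher: the median member of the G2 and M phase list, centred on its mean over the 6 libraries, stood at 2.22 there, at -0.73 and -0.83 in the other parental libraries and between -0.25 and -0.18 in the knockout libraries. Without it, 37 of 41 G2 and M phase genes rose and none fell (camera adjusted p = 0.00058), and 27 of 42 S phase genes rose and 4 fell (0.0219). Without parental replicate 1 or 2 both lists were instead called down, with the adjusted p of each at least 0.00058 and at most 0.225 over the 6 libraries left out in turn. MCM4, at -1.01 (adjusted p = 0.169), was at -0.29 (0.000353) without parental replicate 3, and MCM7, at -0.63 (0.477), was then at 0.38 (2.75e-05). Of 13 cyclin D, CDK and CDK inhibitor genes, CDKN1B rose (0.94, adjusted p = 0.00479), CDKN2D fell (-1.13, 0.0355, and at most 0.136 with 1 library left out) and 11 did not pass; adjusted over the list alone, 1 rose and 0 fell (camera adjusted p = 0.95). Of 6 replication-dependent histone genes none changed by edgeR, with 0 adjusted over the list alone, 1 at an unadjusted p under 0.05, 1 by DESeq2 and 0 by limma-voom; HIST1H1C was at -0.82 (adjusted p = 0.0508) and HIST1H4H at 0.84 (0.202), each called without parental replicate 3 (camera adjusted p = 0.65 for the list). Of the cyclin and CDK genes 7 rose and 4 fell without parental replicate 3, and of the histone genes 1 rose and 2 fell.

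**Figure D3:**
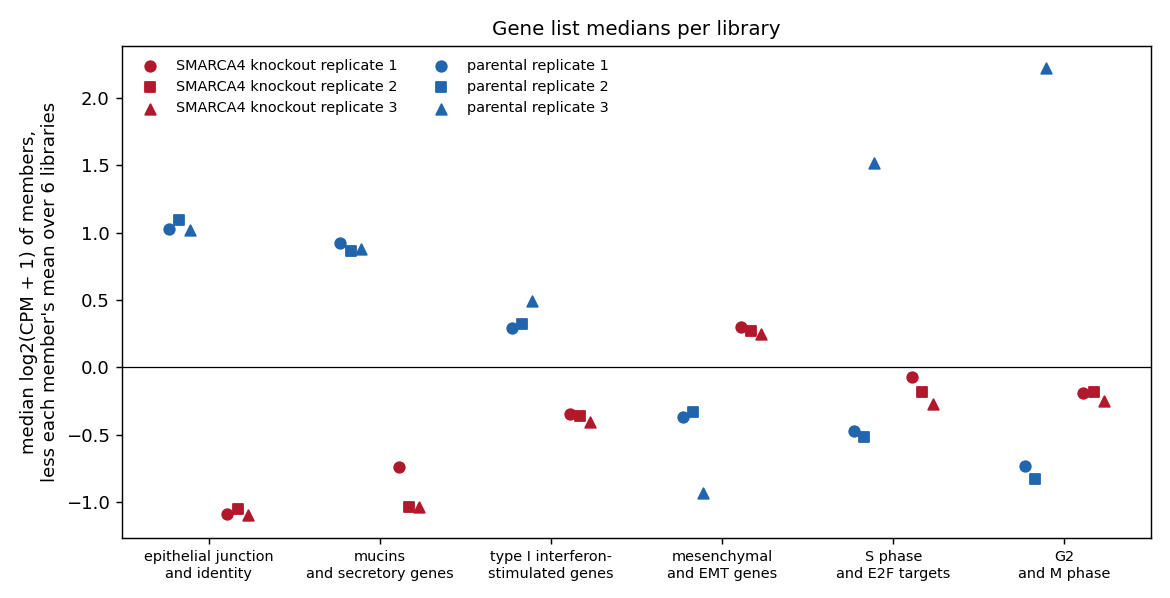
Median over the members of 6 gene lists of log2(CPM + 1), less each member's mean over the 6 libraries, with 1 point per library (parental in blue, SMARCA4 knockout in red; circle, square and triangle for replicates 1, 2 and 3). Parental replicate 3 stood at 2.22 for the G2 and M phase list, above the other 5 libraries, while the 3 parental libraries lay together for the epithelial list (1.02 to 1.09).

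Of 37 NRF2 targets, 10 fell, 7 rose and 20 did not pass, with the same counts adjusted over the list alone (camera adjusted p = 0.338). GPX2, a glutathione peroxidase, fell from 349.6 ± 94.7 to 0.929 ± 0.0953 CPM (-8.55, adjusted p = 2.62e-05), while AKR1C2, an aldo-keto reductase with close paralogs, rose from 1186 ± 115 to 3634 ± 164 CPM (1.62, adjusted p = 0.000415). Of 31 ATF4 and integrated stress response genes, 5 rose, none fell and 26 did not pass, with the same counts adjusted over the list alone. SLC7A5, a large neutral amino acid transporter, rose from 1137 ± 204 to 4290.0 ± 158 CPM (1.92) and NUPR1 changed by 4.81 (5.61 without parental replicate 1). That list's camera call (adjusted p = 0.043, and adjusted p = 0.893 with an estimated correlation) was lost with upper-quartile factors (0.0562), by fry (0.171) and without parental replicate 3 (0.603), where the median of 0.29 became 0.06 and 12 members rose and 14 fell. Of 65 cytosolic ribosomal protein genes, 10 rose, none fell and 55 did not pass, but 4 rose adjusted over the list alone (camera adjusted p = 0.000357, and adjusted p = 0.893 with an estimated correlation). RPL15 rose from 543.3 ± 35.1 to 842.0 ± 53.7 CPM (0.63), a call lost without knockout replicate 1 or 2 (at most 0.0561), and without parental replicate 3 the list had 64 of 65 genes rising and a median of 0.54 in place of 0.36. Fry did not call this list (0.171). Of 55 nuclear genes of oxidative phosphorylation, 5 rose and 50 did not pass, with 0 adjusted over the list alone (camera adjusted p = 0.323). UQCRC1 (0.67) was among them, at an adjusted p of at most 0.0661 with 1 library left out, and without parental replicate 3 the list had 40 genes rising and was called up (0.00356). None of 15 mitochondrially encoded genes changed by edgeR, with 0 adjusted over the list alone, 2 at an unadjusted p under 0.05, 2 by DESeq2 and 0 by limma-voom; MT-RNR2 was at -0.14 and MT-CO1 at -0.18 (camera adjusted p = 0.508). Of the NRF2 targets 14 rose and 16 fell without parental replicate 3, and 2 mitochondrially encoded genes fell.

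Of 31 hypoxia response genes, 3 rose, 3 fell and 25 did not pass, with the same counts adjusted over the list alone (camera adjusted p = 0.886), and SLC2A3, a glucose transporter, stood out at 7.28. Of 20 glycolysis genes, 2 rose, 1 fell and 17 did not pass, with the same counts adjusted over the list alone (camera adjusted p = 0.917); ENO2 changed by 0.77. Of 30 p53 targets, 5 rose, 2 fell and 23 did not pass, with the same counts adjusted over the list alone (camera adjusted p = 0.607); GDF15 rose from 191.0 ± 7.60 to 309.7 ± 13.1 CPM (0.70) and BBC3 changed by 0.87. Of 22 unfolded protein response genes, 3 rose, 1 fell and 18 did not pass, with the same counts adjusted over the list alone (camera adjusted p = 0.338). HYOU1 changed by 0.83, with an adjusted p of at most 0.0519 with 1 library left out. Of 26 apoptosis regulators, 6 fell, 3 rose and 17 did not pass (7 and 4 adjusted over the list alone; camera adjusted p = 0.388), with BIK at -1.74 and HRK at 4.17. Of 24 fatty acid and lipid genes, 5 fell, 1 rose and 18 did not pass, with the same counts adjusted over the list alone (camera adjusted p = 0.338), with PLIN2 at -2.64 and ACACB at 2.48. Of 24 cholesterol genes, SREBF2 (0.99) and STARD4 (3.06, and 3.74 without parental replicate 3) rose and 22 did not pass, with the same counts adjusted over the list alone (camera adjusted p = 0.923). Of 39 DNA damage repair genes, ATM rose (1.30, adjusted p = 0.00131) and 38 did not pass, with the same counts adjusted over the list alone (camera adjusted p = 0.917). Of 34 MYC target and ribosome biogenesis genes, ODC1 rose (0.83, and at most 0.0933 with 1 library left out) and 33 did not pass, with 0 adjusted over the list alone (camera adjusted p = 0.886). Without parental replicate 3 these last 3 lists were called up, at camera adjusted p = 0.00741 for cholesterol, 0.0468 for repair and 0.0405 for MYC targets. The counts rising and falling were then 11 and 10 for hypoxia, 9 and 3 for glycolysis, 14 and 7 for p53 targets, 11 and 5 for the unfolded protein response, 6 and 15 for apoptosis, 9 and 10 for fatty acid and lipid genes, 15 and 5 for cholesterol, 19 and 2 for repair, and 17 and 1 for MYC targets.

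The single genes that rose most, among those with a mean of at least 5 CPM and no overlap between the groups, included MYADM, which encodes a membrane protein. It stood at 117 ± 3.66 CPM in the knockout and 0.0638 ± 0.0278 CPM in the parental group (10.80, adjusted p = 8.98e-06). CRB1 had 3673 reads in the knockout and 3 in the parental libraries, a ratio of 1236 (95% counting interval 422.6 to 5996). All 3 parental reads lay in parental replicate 3, and the log2 fold change of 10.10 became 13.25 without it. TFPI2, an inhibitor of serine proteases, rose from 25.5 ± 15.1 to 3231 ± 170 CPM (6.98, adjusted p = 0.00072). Others were SCARA3, SLC47A1, SHISAL1, KANK4, SLC2A3 and MAPK4, with log2 fold changes from 7.10 to 7.70. With 1 library left out, SCARA3 was at 8.78 without parental replicate 3, KANK4 at 8.17 without parental replicate 1 and SLC2A3 at 8.20 without parental replicate 2. Among the fallers, MIR205HG, the host transcript of a microRNA, had 0 reads in the knockout and 11396 in the parental libraries, so it was at least 3763-fold lower against a limit of 3 counts over the group. UGT1A6 had 1 read against 4367 (ratio 4326, 95% counting interval 776.0 to 170900), but 64.4% of its annotated exon bases are shared with other genes, mainly of the UGT1A cluster. PLA2G4F had 1 read against 4165 (ratio 4126, 740.1 to 163000), of which 2755 lay in parental replicate 3, without which the log2 fold change of -11.57 became -10.61. Genes with a single knockout read moved further when the library holding it was left out, UGT1A6 from -11.63 to -13.52 and PLA2G4F to -13.43. GBP6, a guanylate-binding protein, fell from 49.3 ± 0.223 to 0.0402 ± 0.0353 CPM (-10.17), and PROM2, a membrane glycoprotein, from 164.3 ± 5.63 to 0.226 ± 0.0735 CPM (-9.49). IL1RN, the interleukin-1 receptor antagonist, changed by -9.26, FUT3 by -9.14, TMPRSS4 by -8.91 and NCKAP5 by -8.86 (-9.54 without knockout replicate 1). UCA1, a long non-coding RNA at -10.49, was at 136.9 ± 159.4 CPM in the parental group, so its level differed widely among the parental libraries, and its log2 fold change became -8.93 without parental replicate 3.

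Of the 47 lists with enough members for a test, camera with its preset correlation of 0.01 called 19, 11 up and 8 down. Some lists share members, so these calls are not independent of each other. MX1, for example, is in the RNA sensing and the type I lists, and COL1A1 is in the mesenchymal and the fibroblast lists. The epithelial and the mucin lists are the 2 that were also called with an estimated correlation. Fry called 22 lists, without the extracellular matrix, TGF-beta, ATF4 and ribosomal protein lists but with those of interferon-gamma, cytokines, neuroendocrine genes, hypoxia (0.0357), lung lineage (0.00499), the unfolded protein response (0.0353) and Polycomb and CHD regulators (0.0166). Fry does not compare a list with other genes. The camera direction was up for hypoxia (median -0.09, mean 0.15) and for the cyclin and CDK list (-0.06 and -0.05), and up with a mean below 0 for immediate early genes (0.06 and -0.05) and receptor tyrosine kinases (0.36 and -0.04), none of which passed. The extracellular matrix list was also up with a mean below 0 (0.43 and -0.06), and it did pass (camera adjusted p = 0.0485). In other divisions of the 6 libraries into 3 and 3, edgeR called 0 genes (22 to 824 at an unadjusted p under 0.05). The preset camera test gave between 18 and 23 lists there. List calls that rest on it alone are therefore not separated from the structure of the libraries. Fry and camera with an estimated correlation called 0 lists in each of those divisions. All of those divisions mix the groups, so none of these counts is a value for no change.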

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

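All alternatives here were planned, and none of these tests was chosen only after the result was seen. The 4912 genes changed were 4930 with RLE and 4977 with upper-quartile factors, 4704 with no filter, 3984 with at least 1 CPM in 3 libraries, 5990 with DESeq2 and 4991 with limma-voom. Of these, between 3847 and 4841 were among the 4912. Scaling moved the median log2 fold change of all genes from 0.019 to between -0.033 and 0.065. The fall of SMARCA4 kept its direction and stayed past the threshold in these settings and with the replicate block, from -3.65 to -3.53, as did that of STING1, from -4.02 to -3.91. With 1 library left out they ranged from -3.72 to -3.41 and from -4.14 to -3.73.

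With the replicate number as a block, 3040 genes changed (1378 rising and 1662 falling), of which 3022 were among the 4912. The block takes residual degrees of freedom. Over all genes, deviations from the group mean correlated at -0.05, 0 and -0.07 between libraries of the same number, which gives no sign of pairing. The mitochondrial share of gene reads nevertheless rose with the replicate number in both groups. It was 4.852%, 5.69% and 6.731% in the knockout and 5.565%, 6.325% and 6.41% in the parental libraries. A batch shared by libraries of the same number is therefore not excluded. With the block the extracellular matrix (0.0598) and endothelial (0.0557) lists were no longer called and the interferon-gamma list was (0.0296). Leaving out 1 library gave 2692 to 11325 genes changed, 1221 to 5665 rising and 1471 to 5660 falling. The lowest counts came without a knockout library (2778, 2692 and 2785). Between them came 3594 and 3783 without parental replicate 1 and 2, and the highest came without parental replicate 3. Parental replicates 1 and 2 correlated at 0.9956 with each other and at 0.9591 and 0.9567 with parental replicate 3. The spread within the parental group is therefore smaller without that library. How far this accounts for the counts was not tested. Camera with an estimated correlation called 2 lists in place of 19, and fry called 22.

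A reversal is counted where a gene's log2 fold change, or a list's camera direction, turned and the value before or after passed the threshold. The reversals came without parental replicate 3, and the cause was not tested. With 1 library left out, MCM7 ranged from -0.97 to 0.38, MKI67 from -1.74 to 0.61 and TOP2A from -1.04 to 0.90, each highest without that library. So did the medians of S phase (-1.12 to 0.37), G2 and M phase (-1.74 to 0.59), cholesterol biosynthesis (-0.44 to 0.25), MYC targets and ribosome biogenesis (-0.35 to 0.17) and DNA damage repair (-0.37 to 0.17). For the extracellular matrix list the median ranged from 0.36 to 0.47, but the camera direction turned to a fall without parental replicate 3. For named genes, 966 comparisons with the other settings stayed on their side of the threshold with no such reversal, 24 lost the call and 3 gained it; with 1 library left out, these were 770, 82 and 3, with 3 reversals. For lists they were 329, 31 and 11, and 259, 7 and 10 with 6 reversals. Among those that stayed on their side, the log2 fold change of a gene changed sign in 5 comparisons with other settings and 1 with a library left out, as SMARCA2 did (-0.11 to 0.09), and a list's median in 12 and 11. Depth limits what can be said of CGAS, IFNB1, CXCL10 and CCL5, which had between 0 and 9 reads per library against a limit of 3 counts.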

Other observations

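The tests of gene copy number, of fibroblasts and of another cell line, and the scans of gene families and of neighbouring genes, were chosen only after the result was seen. The tests of GC content and gene length on chromosome 3, and both tests of parental replicate 3, concern patterns found in these data. They were therefore not set before the data were examined.

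Among 226 gene families of at least 8 protein-coding genes, 6 differed from the other genes in how many rose or fell (Fisher's exact test, adjusted over families). This test treats genes as independent, while members of a family can vary together, so its p-values can be too small. Several MUC and KRT genes are also members of the mucin, epithelial and squamous lists, so their calls are not separate from those lists. All 9 MUC genes tested fell (adjusted p = 1.81e-05), and 11 of 22 keratin genes (KRT) fell while 1 rose (0.0298). Of 66 genes with the root RAB, which includes small GTPases of vesicle traffic, 23 fell and 7 rose (0.0298), with RAB25 at -7.78, RAB17 at -4.83 and RAB31 at 3.60. Of 9 genes with the root ITGA, integrin alpha genes with a numbered symbol, 6 rose and none fell (0.0298). Among these risers ITGA11, ITGA10 and ITGA2B had means under 1 CPM in both groups. Zinc finger genes (ZNF) fell less often than others, with 25 of 376 falling and 72 rising (1.05e-05), and so did RPL genes, with 0 of 46 falling and 7 rising (0.0336). RAB25, named after its values were seen, fell from 111.5 ± 22.2 to 0.505 ± 0.0655 CPM.

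Of 137 windows of 20 Mb, 15 differed in their median log2 fold change from permuted gene positions, 9 up and 6 down, with a smallest permutation p of 5e-04, the smallest that the permutations can give. The window medians had an SD of 0.15, against 0.059 to 0.09 in 100 shuffles. The called windows included all of chromosome 3 from 0 to 60 Mb, chromosome 16 from 40 to 100 Mb (194 genes, median 0.31, SE 0.05), chromosome 7 from 20 to 60 Mb (86 genes, -0.43, SE 0.09) and chromosome 8 from 0 to 20 Mb (33 genes, -0.61, SE 0.1). The other 6 called windows lay on chromosomes 1, 5, 6, 8 and 11. For parental replicate 3 against the other parental libraries, 0 windows were called by the same permutation test.

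Neighbouring genes on chromosome 3 shifted together. Of 242 genes at 0 to 60 Mb, 103 rose and 9 fell, with a median log2 fold change of 0.44 (SE 0.03) and 0.48, 0.49 and 0.42 against each parental library. A bias by GC content or gene length is argued against, since the median was 0.53 (SE 0.03) after fitting both. A difference in gene copy number between the cells of the groups is a candidate explanation: 83.5% of the genes lay above 0, and the medians of the 10-Mb parts lay between 0.35 and 0.56. DNA was not used here, and a difference between the cells that were grown into each group, apart from SMARCA4, stays open and untested. The gene lists and families were tested without regard to position, so members lying in a shifted segment can add to their counts.

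In the knockout libraries 32 of 37 epithelial genes fell, and of 29 mesenchymal genes 16 rose, 3 fell and 10 did not pass. Fibroblasts mixed into those libraries are argued against: KRT19 was at 2.36% of its parental level, which dilution alone would need mostly other cells to reach, while COL1A2 and DCN reached at most 0.227 CPM there. Another cell line under the knockout label was not told apart by the genes examined for it, CDKN2A, CDKN2B and MTAP. Genes elsewhere in the genome were not examined for this. CDKN2A and CDKN2B had 1 read in all over 6 libraries, while MTAP beside them was at 72.5 ± 1.34 CPM in the knockout and 88.8 ± 4.91 CPM in the parental group, a state that other lines can share. The knockout itself, the difference the design names, may also be the cause, and stays open.

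Parental replicate 3 stood apart from the other parental libraries, with its G2 and M phase genes higher by a median of 3.20 on the log2 scale. Knockout material mixed into it is argued against: 8 genes at 20 CPM or more in the knockout and under 0.5 CPM in parental replicates 1 and 2 reached a median of 0.726% of their knockout level there, against 0.910% in those libraries. A bias by GC content or gene length is argued against too, with a median of 3.05 (SE 0.1) after fitting both. No biological explanation was tested, since the design names none for this library.

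The 10 divisions of the 6 libraries into 3 and 3 are too few for a share under 0.05. In the real division 4912 genes changed, 2365 rising, 2547 falling and 3031 at least 2-fold, and the highest count in any other division was 0 for each by edgeR, with 22 to 824 genes at an unadjusted p under 0.05. In 1 of the 10 divisions, the real one, these counts were as large as observed. The fall of SMARCA4 was -3.59, where the largest size in another division was 1.22, and that of STING1 was -3.97, where it was 1.39. For lists, 7 of the 10 divisions called at least 19 by camera at its preset correlation, and the highest other count was 23. The preset test therefore does not separate the real division from the others. With an estimated correlation camera called 2 lists in the real division and 0 in each other, and fry called 22 and 0. Each other division mixes the groups and keeps part of their difference, which also widens the spread within its sides. Its counts of genes and lists are therefore not values for no change.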
